A study of Volvox carteri with 4 samples.

How the data were processed

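Volvox carteri was grown in liquid medium at 23 °C under light of 48 µE per square metre and second, per the labels' protocols. Gonidia and somatic cells were separated with a Dounce homogenizer, and RNA was extracted with TRIzol, per the labels' protocols. Small RNAs of 18 to 28 nt were cut from a gel, joined to a 3' and a 5' linker, reverse transcribed and amplified by PCR, per the labels' protocols. For the degradome, poly(A)+ RNA was joined to a 5' linker, amplified and cut with MmeI, an enzyme that cuts a fixed distance into the insert, per the labels' protocols; 99.3% of the deposited degradome reads were 20 or 21 nt long. The submitters' processing notes name Bowtie 1.0.0, with no role. The genome build, the trimming and any filter on reads are not given in the sources used here.

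Each of the 4 deposited files lists distinct sequences and the raw count of reads of each; the authors deposited these counts without normalization. Totals ran from 3356073 to 4527577 reads. Between 0.0505% and 0.264% of reads held the start of the usual 3' linker. The whole colony small RNA file held reads of 18 to 27 nt and the other files reads of 18 to 28 nt. The count of a sequence covers every place in the genome it could come from, and fragments of longer RNAs were not removed.

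Groups were taken from the labels, with 1 library per group and no unassigned sample. With 1 library per group no model was fitted and no p-value between conditions was computed. Levels are reads per 1000000 reads (rpm), with all reads in the file as the total. Shares, levels and ratios have exact 95% Clopper-Pearson intervals (for a ratio, the conditional interval of the gonidia reads among gonidia plus somatic reads). In the ratios given against a floor, 3 reads stood in for a count of 0, which is 0.757 to 0.894 rpm in the small RNA libraries. A sequence of 20 to 22 nt was called higher in one cell type with at least 100 reads in gonidia plus somatic cells, a ratio of at least 2 or at most 0.5 and an interval without equal levels. Overlapping sequences were grouped where they share 16 nt. Degradome tags were compared with 100 dinucleotide-shuffled sets of the 400 small RNAs. The bases before a cut were read from other tags that overlap by at least 14 nt, up to 11 bases. Degradome tags and small RNAs were matched by their first 18 nt where their 5' ends were compared.

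The comparisons, their tests and the rule for naming sequences were fixed before the data were examined. Named were the 10 most abundant 20 to 22 nt sequences by the equally weighted mean of the small RNA libraries, the 8 highest and 8 lowest ratios of gonidia to somatic cells ranked by the interval bound nearest to 1, and the 15 small RNAs with the most tags at the cleavage position. Some sequences that the rule names are not reported here. Other names were chosen after their values were seen. Alternatives fixed in advance were other scalings (reads of 20 to 22 nt, TMM, DESeq2 size factors), other read minimums, a 4-fold threshold, distinct sequences counted once, leaving out the 10 most abundant sequences, other tag minimums, neighbouring positions and reversed sequences as control.

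The rules were tested on simulated data. For gonidia against somatic cells, 200 of 8521 sequences were changed, and the rule called 96% of those changed 3-fold and 100% of those changed 4-fold, 8-fold or 16-fold, with 0 calls among 8321 unchanged sequences. The simulated counts varied by counting error alone, which the rule allows for, so few false calls were fixed in advance. Variation between library preparations was not simulated, so this gives no rate of false calls for the real libraries. In the degradome search over 400 small RNAs, 60 of 60 planted sites were found, and with no planted site 54 of 400 small RNAs (13.5%) still passed by chance pairing. The bases before a cut were read correctly for 200 of 200 simulated transcripts, and 50 of 50 planted duplex partners were found. The simulated transcripts were evenly covered by tags, and planted sites and partners paired fully. These recoveries therefore check that the rules work as written, not how often they succeed in the real libraries.

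No genome was used here, so miRNA loci, small RNAs per gene, the gene lists fixed in advance (which include flagellar, extracellular matrix and photosynthesis genes as markers of the separated cells), complementarity scores against transcripts, and the alternatives that need genome matches were not analysed here. The locus tags and symbols at hand carry no sequence and were not used. The purity of the separated cells was therefore not measured. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 (TMM factors) and DESeq2 1.42.0 (size factors) were used.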

Results

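The series sampled Volvox carteri strain NIES-865, a multicellular green alga whose spherical colonies hold many small flagellated somatic cells and a few large reproductive cells, the gonidia. Small RNAs were sequenced from whole colonies, from gonidia and from somatic cells, and the 5' ends of poly(A)+ RNA were sequenced from whole colonies as a degradome library, which reads the ends left when transcripts are cut. Each of the 4 groups held 1 library. The small RNA libraries held 3356073 reads for whole colonies, 3669462 for gonidia and 3964579 for somatic cells, and the degradome held 4527577 reads. They listed 330745, 223423, 252405 and 1267399 distinct sequences in the same order. No difference between libraries has a replicate check, so differences are given as values with 95% counting intervals (exact Clopper-Pearson) that compare the libraries and cover counting error only, since PCR reads without molecular identifiers are not independent molecules. Sequences are written in DNA letters, and positions in the genome are not given because no genome was used here.

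Volvox small RNAs were mostly 21 and 22 nt long and began with U. Reads of 20 to 22 nt made up 78.6% of the whole colony library (95% interval 78.5 to 78.6%), 84.1% of the gonidia library (84.1 to 84.1%) and 82.1% of the somatic library (82.0 to 82.1%). In gonidia 40.5% of reads were 21 nt and 31.2% were 22 nt, while in somatic cells the shares were 36.2% and 35.6% and in whole colonies 33.7% and 33.9%. Among reads of 20 to 22 nt, 90.8% in whole colonies and 91.5% in somatic cells began with U, against 76.7% in gonidia. C began 18.3% of these reads in gonidia (18.2 to 18.3%), 3.99% in whole colonies and 4.51% in somatic cells. Without the 10 most abundant sequences of each library the share of 5' U in gonidia was 91.7%, next to 90.4% in whole colonies and 92.0% in somatic cells. When each distinct sequence counted once, the share with 5' U was 68.4%, 70.1% and 71.9% in whole colonies, gonidia and somatic cells. The longest reads of the whole colony library were 27 nt, whereas 28 nt reads made up 1.21% of the gonidia and 0.932% of the somatic library.

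**Figure D1:**
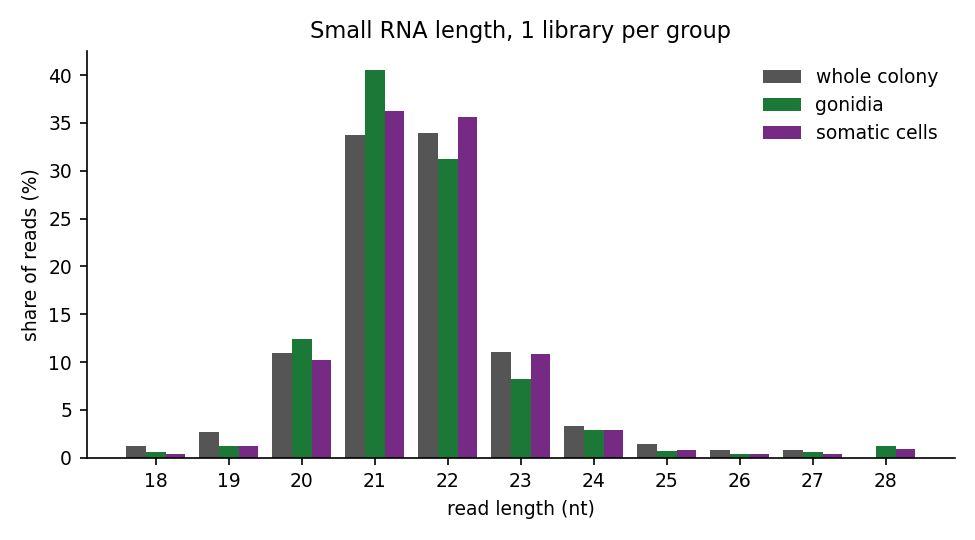
Share of reads (%) at each read length (nt) in the whole colony, gonidia and somatic libraries, 1 library per group. Lengths of 21 and 22 nt lead in each library, from 31.2% to 40.5% of reads.

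The most abundant small RNAs of the series belonged to 1 group of overlapping sequences that dominated the gonidia library. The 4 most abundant sequences by the mean of the 3 small RNA libraries, CCCGACTAAGGATACATCCGC, CCCGACTAAGGATACATCCGCC, CCGACTAAGGATACATCCGC and CCGACTAAGGATACATCCGCC, differ in their ends alone. All reads that hold their shared core CGACTAAGGATACATC made up 13.5% of the gonidia library (13.5 to 13.5%), 1.47% of the somatic library and 0.876% of the whole colony library. The leading form, CCCGACTAAGGATACATCCGC, stood at 45420 reads per 1000000 reads (rpm) in gonidia (45207 to 45633), 4777 rpm in somatic cells and 1912 rpm in whole colonies. The fifth, TGATGGTTGCCGTCATGTCGG, was higher in somatic cells, with 14546 rpm against 6897 rpm in gonidia and 748 rpm in whole colonies. TGCTGGTGGTATGTCACCTAGG, TCCAACTGTATCAGGGTAGTGC, TGGGCCCCAAACGGTCGGTAAC and TAAACTTGCAGGACGCTAACCC, all of 22 nt, were also higher in somatic cells. Their somatic levels were 5644, 5539, 3013 and 3273 rpm, and their gonidia levels were 1117, 393, 1983 and 495 rpm. The difference of 3013 rpm in somatic cells against 1983 rpm in gonidia missed the 2-fold threshold. GCTGGCGGAACTCAAGTCGG was higher in gonidia, with 4045 rpm against 2278 rpm in somatic cells and 1280 rpm in whole colonies, a difference that also missed the 2-fold threshold.

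**Figure D2:**
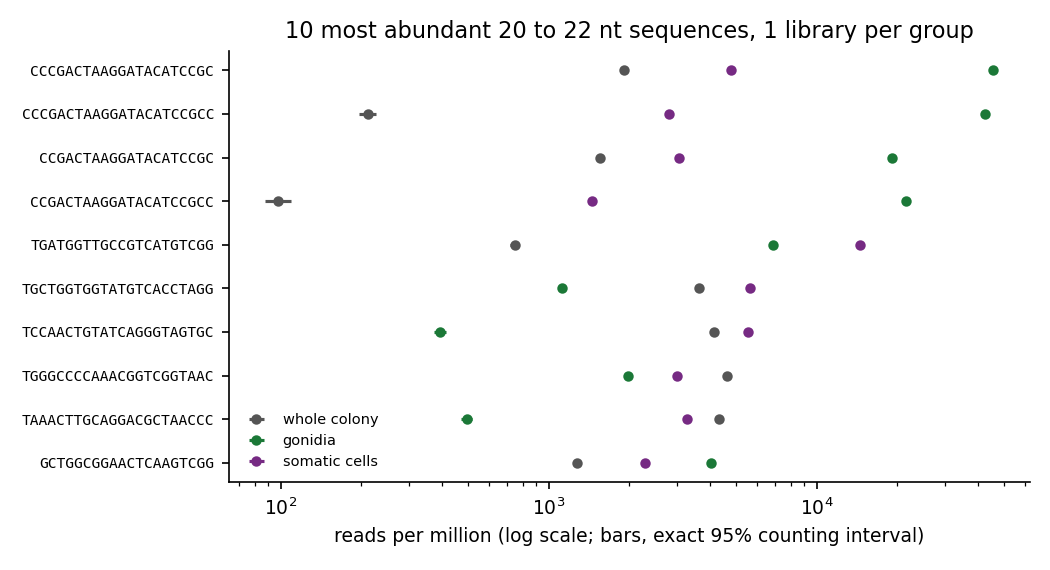
Level (rpm, log scale) of the 10 most abundant 20 to 22 nt sequences in the whole colony, gonidia and somatic libraries, 1 library per group, with exact 95% counting intervals as bars. The 4 leading sequences are highest in gonidia, at 19155 to 45420 rpm.

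The comparison of gonidia with somatic cells asks how small RNAs divide between the reproductive and the somatic lineage. Most abundant small RNAs differed between both libraries. Of 8521 sequences of 20 to 22 nt with at least 100 reads in gonidia plus somatic cells, 2562 (30.1%) were at least 2-fold higher in gonidia and 3178 (37.3%) were at least 2-fold higher in somatic cells, with intervals that excluded equal levels. The other 2781 passed in neither direction. At a 4-fold threshold 1410 were higher in gonidia and 1885 in somatic cells. Overlapping sequences are not independent RNAs, and after summing those that share a stretch of 16 nt, 1451 of 5040 groups were higher in gonidia and 1817 in somatic cells. Among sequences of 22 nt 41.1% were higher in somatic cells and 26.2% in gonidia, among those of 21 nt 34.5% and 32.5%, and among those of 20 nt 35.2% and 33.7%. With DESeq2 size factors the shares were 37.3% and 29.4% at 22 nt, 30.9% and 36.0% at 21 nt and 31.3% and 37.3% at 20 nt, so gonidia calls became the more frequent at 20 and 21 nt. The median log2 ratio of gonidia to somatic cells was -0.24 when scaled to all reads. DESeq2 size factors centre this median by construction (-0.01), and with them 2850 sequences were called higher in gonidia and 2858 in somatic cells. Small ratios and the excess of somatic calls thus depend on the scaling.

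The single sequences most enriched in the gonidia library were rare in or missing from the somatic library, but overlapping forms of some were not. TGACACCAAACATGTTCAAGG was the most abundant, at 1350 rpm in gonidia, 26.7 rpm in somatic cells and 23.5 rpm in whole colonies, a ratio of 50.5 (41.7 to 61.8). AGGGGGACGGTGGATTTGGGCA, TGCCACCTCAGCAGGTCGACA and TTCTTCGTCTAGTAAGTTGAG had 0 somatic reads beside 275, 136 and 121 gonidia reads. With a floor of 3 reads in place of 0 their ratios were 43.6 or more, but their 95% intervals start below these ratios, at 80.0, 39.3 and 34.9. The first and the third each make up only part of a group of overlapping sequences. Summed over the group, the first had 7365 reads in gonidia and 768 in somatic cells, a ratio of 10.4 (9.62 to 11.2). The third had 581 and 58, a ratio of 10.8 (8.25 to 14.4). For TGACACCAAACATGTTCAAGG the summed ratio was 33.7 (28.9 to 39.5). TTCATGGCAACATGTCATTGG had 291 gonidia reads and 1 somatic read, a ratio of 314 with an interval of 56.0 to 12460.

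The 8 sequences most enriched in the somatic library were rare in or missing from the gonidia library. TGTGCTGAGACCGTGTGCTGT stood at 1323 rpm in somatic cells, 3.82 rpm in gonidia and 334 rpm in whole colonies, a somatic to gonidia ratio of 347 (206 to 635). ATGACCTGCTCGCCATATGCC stood at 583 rpm against 2.45 rpm, a ratio of 238 (125 to 520), and was at 798 rpm in whole colonies. TGGCATGTACCACACTCAAGGC had 462 rpm against 1.91 rpm, a ratio of 242 (117 to 603), and TACAGATATCCTACACTGAAGG had 304 rpm against 1.09 rpm, a ratio of 279 (109 to 1026). ACGTGTGCTGAGACCGTGTGC, which overlaps the first of these sequences, and TGATGACATTGTGGGAGGCAGC had 681 and 363 somatic reads and 0 gonidia reads. With the floor of 3 reads in place of 0 their ratios were 210 and 112, and their 95% intervals start lower, at 170 and 90.6. GCAGTGGTGCCACTCCCGTTGG had 994 somatic reads and 3 gonidia reads, a ratio of 307 (105 to 1490), and TGAATGGATGTTGCCGATTGCG had 573 and 1, a ratio of 530 (94.8 to 20984).

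**Figure D3:**
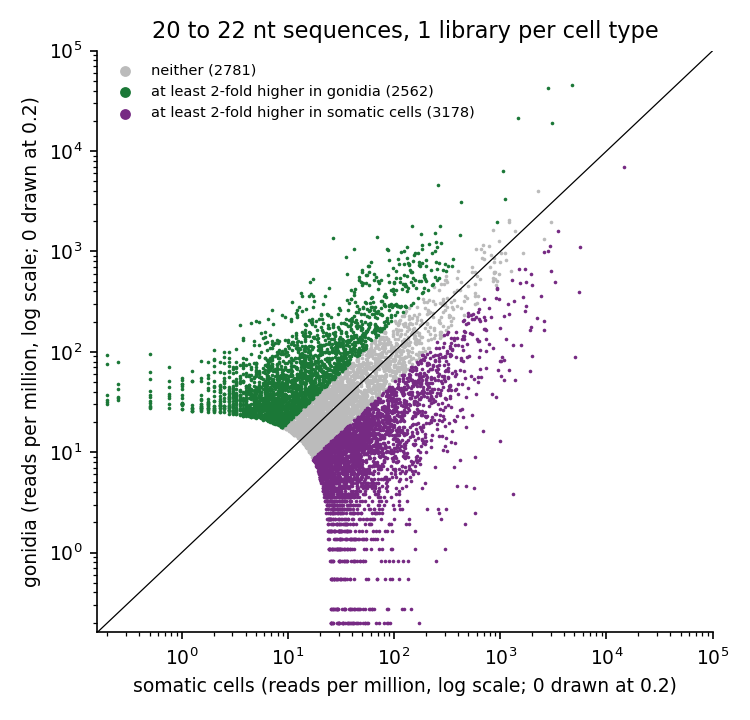
Level of each of 8521 sequences of 20 to 22 nt in the gonidia library (y axis) and the somatic library (x axis), both in rpm on log scales with 0 drawn at 0.2, 1 library per cell type. Green points are the 2562 sequences at least 2-fold higher in gonidia, purple points the 3178 at least 2-fold higher in somatic cells, grey points the 2781 others, and the line marks equal levels.

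Whole colonies hold both cell types, so their levels were set against those of the separated cells. The whole colony library lay nearer to the somatic library: on the log2 scale 63.4% of 12063 sequences with at least 100 reads over the 3 libraries were closer to their somatic than to their gonidia level. Across sequences, Spearman's rho was 0.76 between whole colonies and somatic cells, 0.49 between whole colonies and gonidia, and 0.50 between gonidia and somatic cells, each over the 3927 to 4731 sequences with at least 100 reads in the third library; sequences are not independent replicates. Equal levels in gonidia and somatic cells with counting error alone gave a simulated rho of 0.99. The whole colony level lay between the gonidia and somatic levels for 5163 sequences, or 42.8% (41.9 to 43.7%), where independent orders of 3 values give 33.3%. Among sequences that differed at least 4-fold between the cell types the share was 64.4%, but a wide gap by itself holds more values: when whole colony levels were exchanged between sequences 100 times, a check added after seeing the data, the mean share was 50.8% in this set and 31.9% over the 12063 sequences. A mixture of both libraries fitted the whole colony levels best with a gonidia share of -0.01, which was 0.47 without the CGACTAAGGATACATC group and 0.23 on log2 levels, so the fit gives no stable share.

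For 3701 sequences the whole colony level was above both cell types, and for 2117 of them the intervals did not overlap. TAAGACAACACCATAACGGCA stood at 5068 rpm in whole colonies and at 298 rpm in gonidia and 579 rpm in somatic cells. TTTAAATGCTGTTGCCTTGGCC stood at 2959 rpm against 52.3 and 1383 rpm, and TGACAGAGCGGAAGCGTGGAGT at 2867 rpm against 918 and 819 rpm. These sequences were chosen after their values were seen. The 21 nt form of the second, without its last base, stood at 2578, 633 and 2978 rpm in whole colonies, gonidia and somatic cells. Summed over its group of overlapping sequences, the second made up 0.616% of whole colony, 0.0750% of gonidia and 0.479% of somatic reads. Its excess over somatic cells was thus smaller than for the single sequence. The group of the first made up 0.576%, 0.0307% and 0.0735% in the same order. A further 3199 sequences were below both cell types in whole colonies, 1358 of them with intervals apart.

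The degradome asks which small RNAs come with cut transcripts. A small RNA that guides cleavage leaves a 5' end opposite its nucleotides 10 and 11, so tags were sought whose first 10 nt pair with nucleotides 1 to 10 of the 400 most abundant 20 to 22 nt sequences with distinct starts. Such tags made up 15448 reads, against 1631 to 3323 reads at the 10 other positions, opposite nucleotides 11 to 20, and a mean of 2245 and at most 9405 reads over 100 dinucleotide-shuffled sets. At least 5 tags were found for 129 of the 400 small RNAs (32.3%, 27.7 to 37.1%), against 73 to 94 at the other positions and a mean of 67.0 in the shuffled sets, whose highest count was 86 (one-sided permutation p = 0.0099, the smallest that 100 sets can give). The other positions all exceeded the shuffled mean, and those opposite nucleotides 15 (93) and 20 (94) exceeded the highest shuffled set. This p-value alone therefore does not single out the cleavage position, although its 129 was above every other position. As counts expected by chance, the shuffled mean and the other positions gave 67.0 to 94, and reversed sequences, a control fixed in advance, gave 41. Some tags at other positions lie at the cleavage position of a shifted form of the same RNA. The number passing by chance is therefore known only roughly. At least 100 tags were found for 18 small RNAs, against a mean of 2.21 and at most 8 in the shuffled sets (one-sided permutation p = 0.0099, again the smallest possible). The 10 leading small RNAs held 78.0% of the tag reads. Of the 18, which include overlapping forms of the same RNA, 11 were at least 2-fold higher in somatic cells (61.1%) and 3 in gonidia (16.7%). The shares were 38.7% and 35.1% for the 111 with 5 to 99 tags and 39.5% and 30.6% for the 271 with fewer than 5, and the difference was not tested.

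**Figure D4:**
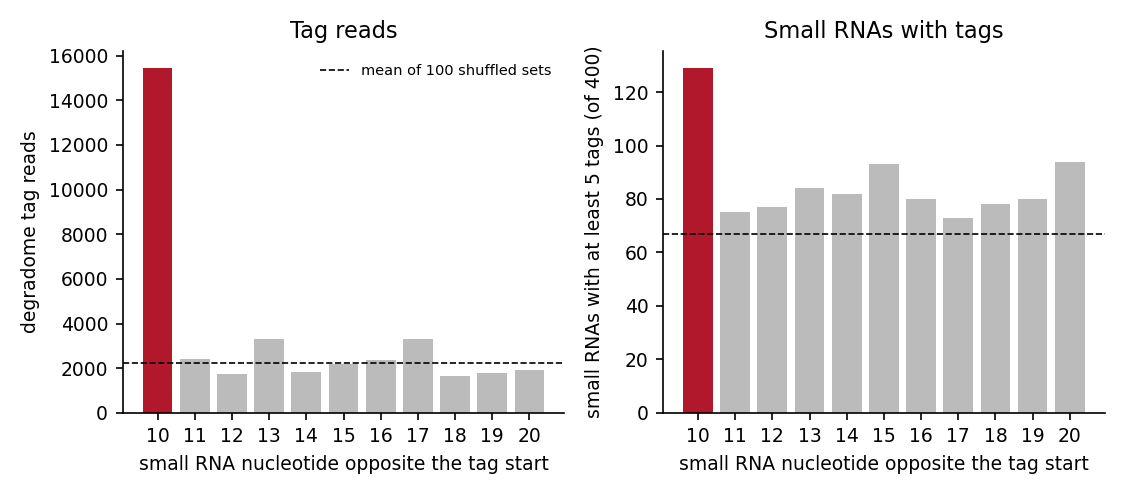
Degradome tag reads (left) and number of small RNAs with at least 5 tags, of 400 (right), by the small RNA nucleotide opposite the start of the tag, with the mean of 100 shuffled sets as a dashed line. Position 10 (red) holds 15448 reads and 129 small RNAs, above each of the positions 11 to 20 (grey).

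The small RNAs with the most tags differed in how many tags lay at other positions. TGACAGAGCGGAAGCGTGGAGT had 2404 tag reads, 531 rpm of the degradome (510 to 553), of which 94.4% were the tag CGCTCTGTCAGTCCTCCCGT, and at most 10 reads at any other position; it stood at 918 rpm in gonidia and 819 rpm in somatic cells. TAGTAGGATCCAGATAGCGGTG and TAGGATCCAGATAGCGGTGC, which starts 3 nt further along the same RNA, had 2390 and 1804 tag reads at their own cleavage positions, so the first has 1804 reads at another position. Both were higher in somatic cells, at 493 against 193 rpm and at 361 against 216 rpm; the second difference was 1.67-fold and missed the 2-fold threshold. TTTAAATGCTGTTGCCTTGGC had 1776 tag reads, and 669 at another position, and stood at 2978 rpm in somatic cells and 633 rpm in gonidia. Its main tag, AGCATTTAAATGCTGTTATGG, also holds the first 13 nt of the small RNA itself. TGGAGAGTAACTCCTGGAGTTG, TGCGGTATGCTTCAATGGCAGC and TGGATGGCAAGCCGCCACTGG had 1237, 878 and 331 tag reads, against up to 1463, 32 and 22 at another position, and were 3.90-fold, 3.69-fold and 4.62-fold higher in somatic cells. TCGCCAGGAAGGCACGAAGTGC and TAAGTCAGGTACAGGCTTTGG, with 806 and 211 tag reads, were higher in gonidia, by 2.35-fold and 5.83-fold.

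The other pairs had fewer tags. TCAGGTGAAGCGACTGTAGGCG, TGGCACTGCATCCGTTAGGTG and TACATTCTGACAGAGCCGTCT had 207, 173 and 153 tag reads. TACCGACCGTTTGGGGCCCATT had 149, and its site strand was also read 38977 times as small RNA. TCTTGGTCAGCACCATGCTGA had 133 tag reads, its site strand was also read 496 times as small RNA, and its main tag CTGACCAAGACTTACGAAGTG begins with the end of its duplex partner AGCATGGTGCTGACCAAGACT. It was 56.1-fold higher in somatic cells (5013 against 89.4 rpm), and TTGCCATGGGCTGCCATATGTC, with 129, was 18.4-fold higher there. The transcripts behind these tags are not named, since the tags were not matched to a genome. As the degradome was made from whole colonies, it does not show in which cell type a transcript was cut.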

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

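The 3 results here come from data outside the comparisons and lie above the floor of 3 reads. The tests below were chosen after the results they address had been seen, except the test of tags at duplex partners.

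An RNA of 28 nt, outside the class of 20 to 22 nt, was among the most abundant sequences of the separated cells. TGTGTGGATGCTGGAGCATATCCGTTGG stood at 5989 rpm in gonidia and 6161 rpm in somatic cells, with 0 reads in the whole colony library, whose reads end at 27 nt. Its 27 nt form stood at 2247, 223 and 206 rpm in gonidia, somatic cells and whole colonies, and its 20 nt form TGTGTGGATGCTGGAGCATA at 4588, 260 and 1271 rpm. The 20 nt form differed between the cell types while the 28 nt form did not differ 2-fold.

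Fragments of 2 RNAs were abundant in the whole colony library and nearly missing from the separated cells. Reads holding AACTCTCAACAACGGATA numbered 5680 in whole colonies, 11 in gonidia and 63 in somatic cells, and the same stretch was the start of the most abundant degradome tags, with 300538 degradome reads. Reads holding CGTGTTGCTATAAGATTT numbered 4210, 4 and 31 in the same libraries, with 14 degradome reads.

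Degradome tags often started at the 5' ends of small RNAs themselves. Of 362 abundant small RNAs of 21 or 22 nt, 85 had at least 5 tags with the same first 18 nt, against 18, 14 and 15 when the start was moved by 1, 2 or 3 nt. Small RNA carried into the degradome library would give tags in proportion to reads, but 6 of the 20 most abundant whole colony small RNAs had under 10% of the proportional number: TGCTGGTGGTATGTCACCTAGG had 12769 reads and 0 tags, while TAAGACAACACCATAACGGCA had 19268 reads and 299 tags. A candidate explanation is that the tags are ends left when hairpins are cut from longer poly(A)+ RNA, which predicts more tags per read at the less abundant strand of a duplex. Over 145 pairs, some of which overlap, tags per 1000 whole colony reads were 17.1 at the partner and 4.05 at the abundant strand, a ratio of 4.22 (bootstrap 95% interval over pairs 1.90 to 8.04). With each duplex counted once, an alternative chosen after seeing the data, the ratio over 129 duplexes was 3.78 (1.70 to 8.02). This does not decide it, since the partner is by choice the strand with fewer reads, and tags that do not follow reads then give a ratio above 1. The partners had fewer tags, 383 against 1229, and with the start moved by 1 or 2 nt they had 40 and 116. The explanation stays open.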

How the results depend on the processing

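The alternatives that sum overlapping sequences, leave out the CGACTAAGGATACATC group, change the number of small RNAs searched, ask for 100 tags or choose sequences for the correlation were chosen after seeing the data. Scaling by reads of 20 to 22 nt, TMM or DESeq2 size factors, or without that group, kept both counts of sequences higher in gonidia or somatic cells within 1.5 times, with 2507 to 2850 and 2858 to 3236. The excess of somatic calls shrank with the scaling: the counts were 2776 and 2931 with TMM, and 2850 and 2858 with DESeq2 size factors. With at least 30 reads the counts were 6633 and 8285, and with no minimum 13780 and 17428, since more sequences were tested; at 4-fold they were 1410 and 1885, and with overlapping sequences summed 1451 and 1817. Counting each distinct sequence once, the share of 20 to 22 nt was 63.0% in whole colonies, 70.9% in gonidia and 69.0% in somatic cells, and that of 5' U 68.4%, 70.1% and 71.9%. Without the 10 most abundant sequences these shares were 78.1%, 81.8% and 81.7%, and 90.4%, 91.7% and 92.0%. The whole colony lay between the cell types for 49.4% of sequences with at least 1000 reads and 64.4% of those that differ 4-fold, next to 39.4% and 50.8% on average when whole colony levels were exchanged between the sequences of each set, a check chosen after seeing the data. The fitted gonidia share was -0.012 when scaled to reads of 20 to 22 nt, -0.015 with at least 1000 reads, -0.046 over sequences that differ 4-fold, 0.47 without the group and 0.23 on log2 levels, next to -0.014 in the fit reported. Spearman's rho of gonidia and somatic levels was 0.32 with at least 1000 whole colony reads, 0.49 over sequences with 5' U and 0.058 over sequences chosen by gonidia plus somatic reads, a choice that itself lowers rho because a sequence low in one library passes only if high in the other. Cleavage positions with tags numbered 85 at a minimum of 10 tags, 225 at 2 and 18 at 100. They numbered 332 with 1 nt on either side also counted, where 1 side was matched more loosely, over 1 nt less. Among 100 small RNAs they numbered 38, and among 1000 they numbered 323. Observed counts exceeded the shuffled mean under each of these, by 1.11-fold with 1 nt on either side to 8.14-fold at 100 tags (one-sided permutation p = 0.0099 in each), next to 1.93-fold in the search reported, and were 3.15-fold those of reversed sequences; the cause of the larger excess over reversed sequences was not tested. Not run, for want of a genome, were the alternatives on miRNA loci, gene lists, complementarity scores, genome matches, counting by locus, removal of annotated rRNA and tRNA, and the tag maximum of a transcript. No paired analysis was possible because each group held 1 library. No library can be left out for the same reason. Depth limits the largest ratios: with 0 to 3 reads in one library their intervals are wide, as for TTCATGGCAACATGTCATTGG (56.0 to 12460).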

Other observations

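The duplex, strand and pairing results in this part were chosen after seeing the data, as were the tests of the abundant group, of counting error and of carry-over at the rate of the leading degradome tag. The tests of scaling and the other tests of carry-over from the degradome were set before their values were seen.

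Many abundant small RNAs had a partner that would leave 2 unpaired nt at the 3' end of the small RNA, as in duplexes left by Dicer enzymes. The 3' end of the partner was not tested. Of the 400 most abundant small RNAs of 20 to 22 nt, 150 (37.5%, 32.7 to 42.4%) had such a partner of at least 10 reads, pairing over 16 nt with at most 1 mismatch. With 0, 1, 3 or 4 unpaired nt the counts were 45, 55, 64 and 56, and in 50 shuffled sets the mean was 0.38 and the highest count 2. An example is TGGGCCCCAAACGGTCGGTAAC with TACCGACCGTTTGGGGCCCATT, at 4633 and 550 rpm in whole colonies. The median share of the partner among the reads of both strands was 1.31%. Of the 16 sequences with the highest or lowest ratios of gonidia to somatic cells, 9 had a partner.

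Both strands of a duplex moved together between the cell types. Over 76 duplexes with enough reads (at least 100 and 20 gonidia plus somatic reads for the strands), the log2 ratios of gonidia to somatic cells of both strands had a Spearman's rho of 0.83 and a Pearson's r of 0.86 (two-sided permutation p of the rho = 1e-05, the smallest that 100000 permutations can give), and 66 of 76 had the same sign. This is across duplexes within a pair of libraries. The 2 strands are separate counts, so counting error in one does not enter the other. For TACAGATATCCTACACTGAAGG and its partner TTCAGTGTAGGATATCTGTACC, the reads were 4 and 26 in gonidia and 1206 and 1440 in somatic cells.

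The balance between the strands differed between the gonidia and somatic libraries beyond counting error for 56 of 142 pairs with at least 100 reads in each. With each duplex counted once it did so for 48 of 124. In 3 of the 142, and the same number of the 124, the partner's share differed by over 20 percentage points. The partner TGACTTTACTCGCCGAAGTAC of TATTTCGGCGAGTAAAGTCAGC made up 57.4% (55.4 to 59.3%) of both strands in gonidia and 29.1% (27.1 to 31.3%) in somatic cells, and the partner TGCGAATCAGGGTTGGCTAT of TAGCCAACCCTGGTTCGCAGA made up 55.0% (53.2 to 56.8%) and 26.8% (25.3 to 28.3%). The third, AACTGCTGCCGAACAGGGAGGCC with TCCCTGTTCGGCAGCAGTTGG, made up 3.92% and 25.4%.

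At some of the candidate cut sites the other side also paired with the small RNAs. Where at least 9 bases before the cut could be read from overlapping tags, for 76 of the 129 small RNAs with tags, 57.8% of the bases opposite nucleotide 11 onward paired on average, G with U included, against 39.97% after exchanging sites between small RNAs (one-sided permutation p = 1e-05, the smallest that 100000 permutations can give). Pairing reached at least 90% at 21 sites, against 0.318 by exchange. The mean includes these 21 sites, and the other sites were not compared alone. Among the named pairs it was 11 of 11 bases for TAGTAGGATCCAGATAGCGGTG, TTTAAATGCTGTTGCCTTGGC, TGGAGAGTAACTCCTGGAGTTG, TCGCCAGGAAGGCACGAAGTGC and TAAGTCAGGTACAGGCTTTGG, of which the last 2 were also read 16 and 7 times as small RNA on the site strand, and 10 of 10 for TAGGATCCAGATAGCGGTGC. For TGGCACTGCATCCGTTAGGTG and TGGATGGCAAGCCGCCACTGG it was 7 and 6 of 11. For TGCGGTATGCTTCAATGGCAGC it was 4 of 11, and 11 of 11 when 1 nt of the small RNA was skipped. For TACATTCTGACAGAGCCGTCT it was 1 of 11. A site with full pairing can also be the opposite arm of the small RNA's own precursor, and the main tags of TACCGACCGTTTGGGGCCCATT and TCTTGGTCAGCACCATGCTGA begin with the end of their duplex partners. Without sites whose strand was also read as small RNA 57.1% of bases paired, over 40 sites, of which 10 reached at least 90%.

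Scaled to all reads, the median sequence was lower in gonidia than in somatic cells, with a log2 ratio of -0.24. A candidate explanation is that the CGACTAAGGATACATC group, 13.5% of the gonidia reads, takes reads from all others in a library of fixed size. Without the group the median was -0.058, but leaving it out shifts each other ratio by the same amount, which the shares of the group fix in advance (0.188), so this does not test the explanation, which stays open. Whether gonidia truly hold so much of this RNA stays open with 1 library. Of the reads of the group 62.4% started at the commonest position, against 32.1% for the group of GCTGGCGGAACTCAAGTCGG and 72.2% to 99.8% for the other 10 of the 12 groups with the most abundant leading sequences.

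Many sequences were above both cell types in the whole colony library. Counting error does not account for it, since for 716 sequences the intervals were more than 2-fold apart, and a single scaling factor does not either, since 1358 sequences lay below both cell types with intervals apart. Tags carried over from the degradome library would share their starts with these sequences. Of the 716, 59.2% shared their first 18 nt with a tag, between the 50% and 90% bounds set beforehand, but 292 shared none, and of the 424 that did 415 (97.9%) had fewer tags than whole colony reads with the same start, which argues against carry-over for these. For the other 9, which include 3 forms of AACTCTCAACAACGGATATC (272015 tags and 4814 whole colony reads with the same start), carry-over stays open. At the rate of that tag, 15 of the 20 most abundant other tag starts had under 10% of the whole colony reads expected, a count that only reaches the limit of the test and includes shifted forms of the same RNA, while TTTACGGAGAAATTAAAA had 1424 against 1475 expected. Culture stage, the separation of the cells and differences between library preparations cannot be separated from the groups, and no biological explanation was tested.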
